A study of Mus musculus with 6 samples.

How the data were processed

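Poly(A)-primed 3' RNA-seq had been carried out on mouse Eµ-Myc B-cell lymphoma cells, a line from tumours driven by a Myc transgene that is active in the B lineage. The cells carried floxed alleles of the miR-17~92 microRNA cluster and a Cre recombinase that 4-hydroxytamoxifen (4-OHT) switches on. Per the labels, 3 libraries came from floxed cells (fl) and 3 from cells deleted for the cluster (del). The deletion had been made with 250 nM 4-OHT, and the treated cells had then been subcloned. All cells had been grown for 48 hours on irradiated fibroblast feeder cells before RNA was taken. The labels do not say whether the 3 libraries of a group came from separate cultures or clones, so the p-values measure the spread between these samples, which may be technical. Because the del cells alone had been treated and subcloned, deletion, treatment and subcloning cannot be separated in this design.

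Per the labels' protocols, complementary DNA was primed with barcoded oligo-dT, samples were pooled, and strand-specific libraries were made from the 3' ends of the transcripts. The table deposited by the authors holds raw read counts per gene for the 6 libraries. STAR, HTSeq and the mm10 build are named in the submitters' processing notes. Their versions and settings are not given in the sources used here. The table has 24885 rows, of which 24052 carry an NCBI gene number and 833 a RefSeq accession. Gene symbols were taken from the RefSeq gene table of the GRCm38 assembly, which matched 23969 of the gene numbers and left 83 unmatched. No count was recorded in any library for 10126 rows. Unmatched gene numbers held 0.204% to 1.03% of the counts of a library. Coordinates are those of GRCm38, the assembly that mm10 represents.

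Total counts were 9580630, 8895138 and 6554423 in the fl libraries and 3738720, 2121796 and 3592196 in the del libraries, so that the fl libraries were on average 2.65 times as deep. Depth and group therefore go together. All intervals and floors given cover counting error only, since reads amplified by PCR are not independent molecules.

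Groups were compared with edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr by group, libraries were scaled with TMM factors, and the robust quasi-likelihood F test (glmQLFit and glmQLFTest) was run with group as the only term. Benjamini-Hochberg adjustment covered all genes tested, with a threshold of 0.05. Every adjusted p given for a gene comes from this test. Standard errors of log2 fold changes were derived from the F statistic. Levels are CPM (counts scaled to a common library total) computed from the deposited counts with the TMM-scaled library sizes. A gene at 0 in a whole group is given as a lower bound against a floor of 3 counts over the group, and a gene with 1 to 3 counts in a group as a ratio with an exact 95% Poisson interval. In simulated counts with the real means and depths, 200 of 10126 tested genes were changed by known amounts in the comparison of del with fl. The test recovered 10.9% of those changed 1.5-fold, 78.5% of those changed 2-fold and 96.9% of those changed 4-fold, and 0.826% of its calls were false. In the real comparison far more genes were called (6676 of 10260), some with larger changes. These rates may therefore not carry over to it.

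The groups, tests, alternative settings, named-gene rule and 36 gene lists were fixed before the data were examined, the lists covering metabolism, signalling, stress, cell cycle, immune and cell type markers and reported targets of the cluster. Of these, 34 had at least 3 tested members and were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 34 lists. The erythroid list had too few tested members, and the mitochondrially encoded mRNAs were not analysed here. Of the B cell list, Ighm, Ighd and Igkc were not analysed here. Estimated correlations and the fry test were alternatives. The named genes were fixed by rule: Mir17hg and Myc, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 20 CPM and no overlap between the groups, and up to 4 members of each list by smallest adjusted p. Other genes named were chosen after their values were seen. Some genes and families that these rules or tests cover are not reported here.

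Targets of the cluster were tested through seed sites. The longest annotated 3' UTR of at least 50 nucleotides was taken for each gene from the GENCODE annotation of GRCm38. The log2 fold changes of 9860 genes were fitted on the presence of a site, log10 UTR length, UTR GC content and mean log2 CPM. The t statistic of the site, its coefficient over its standard error, was ranked among those of 239 to 449 control heptamers. These had the same bases and the same number of CpG. The rank was two-sided, with Benjamini-Hochberg adjustment over 4 families. On 9745 simulated genes, a shift of 0.3 was estimated as 0.312 and no family was called without a shift. These fold changes came from the simulated counts with 200 changed genes, far fewer than the 6676 called in the real comparison. The lack of false calls may therefore not carry over to it.

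The alternative settings were other scalings (RLE, upper quartile, library size), no count filter or a stricter one, DESeq2 1.42.0, limma-voom, stricter thresholds, the replicate number as a block, other site and UTR definitions, and leaving out each library. Thinning every library to 2121796 counts, and removing each library's trend on transcript length and GC content, were added after the data were seen. Pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 7.35 to 30.5), so no pair was taken for the same library, which does not show that they came from separate cultures. Transcript length and GC content were those of the longest annotated transcript of each gene, which need not be the one expressed. Length was examined with random lists matched on 10 length and 5 expression classes (10000 draws). In simulated fold changes with a length trend alone, 3 of 34 lists of 10220 genes lay outside their matched range, the ribosomal proteins among them, and a list shifted by 0.6 was found. Chromosome medians were compared with 10000 expression-matched random sets, and in simulated fold changes of 6044 genes a shifted chromosome was found with 1 other of 20 outside its range. Whether a mixture of cells could give the identity differences was tested by counting genes below 5% of their level in the other group. After that count was known for del, a second measure was tried, the 20th-lowest ratio of del to fl (8.78%). Under the bound first set for it, it argued against a mixture where the count had left the question open, so it was not used for the verdict. A later test counted the genes under 5% by more than the spread between libraries and an exact counting bound, adjusted for the number of genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps and the plots.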

Results

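The series profiled 3' RNA of mouse Eµ-Myc lymphoma cells with floxed alleles of the miR-17~92 cluster (fl, 3 libraries) and, per the labels, of such cells after deletion of the cluster and subcloning (del, 3 libraries). The study's title names tumour metabolism as its subject, and the comparison asks which transcripts differ once the cluster is lost. The libraries held 6554423 to 9580630 counts in fl and 2121796 to 3738720 in del. Values are CPM as mean ± SD with n = 3 libraries per group, and log2 fold changes are del minus fl with standard errors.

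Mir17hg (gene number 75957), the host transcript of the cluster, was at 259 ± 6.0 CPM in fl and 175 ± 28.0 CPM in del (log2 fold change -0.56 ± 0.15, adjusted p = 0.00844, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It lies on chromosome 14 from 115044390 to 115046728, and its end is 2222 bases past the end of Mir92-1, the last microRNA of the cluster. Its level was 252, 263 and 262 CPM in the fl libraries and 167, 152 and 206 CPM in the del libraries. A 3' tag past the cluster does not check the deletion. Of the microRNA genes, Mir18 had 2, Mir19a 3 and Mir19b-1 2 counts over the fl group and 0 over the del group, too few for a test, and Mir17, Mir20a and Mir92-1 had 0 in both. Myc, the driver of these tumours, was at 468 ± 59.9 CPM in fl and 423 ± 28.2 CPM in del (log2 fold change -0.15 ± 0.15, adjusted p = 0.399).

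The groups differed across most of the expressed genome, and the differences included genes that mark cell types. In del, the chemokine receptor genes Ccr1 and Ccr2, the lysozyme gene Lyz2 and the NADPH oxidase gene Cybb rose from near 0, while the epithelial adhesion gene Epcam, the keratin gene Krt18 and the alpha-fetoprotein gene Afp fell to near 0. Of 10260 genes tested, 6676 (65.1%) passed the threshold, 3333 higher and 3343 lower in del. Of these, 2195 were higher and 1629 lower by at least 2-fold, and 322 were higher and 208 lower by at least 16-fold. The 3 fl and 3 del values did not overlap for 7171 genes (69.9%), where chance gives 10%. The first principal component held 90.0% of the variance and separated the groups.

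Lyz2 was at 0.371 ± 0.23 CPM in fl and 454 ± 44.5 CPM in del (log2 fold change 10.19 ± 0.31, adjusted p = 7.17e-08), and Cybb was at 1.97 ± 0.814 CPM in fl and 1470 ± 398 CPM in del. Ccr1 had 1 count over the fl group, a ratio of 3954 in favour of del (95% counting interval 709.7 to 156200), and Ccr2 had a ratio of 2612 (468.7 to 103200). Wfdc17 had no count in fl and was at least 414.5-fold higher in del. Phactr1, Ms4a6c, Nrp1, Cd209a and Marchf1, which encodes a membrane ubiquitin ligase, completed the 10 largest rises. Epcam was at 170 ± 5.02 CPM in fl and had 2 counts over the del group, a ratio of 816.9 in favour of fl (226.2 to 6746). Krt18 was at 214 ± 14.02 CPM in fl and 0.606 ± 0.425 CPM in del (log2 fold change -8.37 ± 0.28), and Afp had a ratio of 444.3 in favour of fl (152 to 2154). Ppm1j, Cttn, Cxcr2, Trpa1, Tes, Tspan8 and Tmem37 completed the 10 largest falls, with Cxcr2 going from 79.3 ± 18.5 CPM to 0.426 ± 0.145 CPM.

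Genes of B cell identity were higher in del. Of 28 tested members 27 rose and none fell (27 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 4.74, also with Rag1 at its lower bound (camera, adjusted p = 1.54e-12). The call was lost with an estimated correlation (camera, adjusted p = 0.135). It was kept with fry, which does not compare a list with other genes (adjusted p = 1.07e-05). Each of the other splits of the libraries into 3 and 3 also called 6 to 14 of the 34 lists. Passing the list threshold, here and below, is thus not particular to the grouping into fl and del. Those splits hold fl and del libraries in unequal number in each group and keep part of their difference. They therefore do not show whether a given call depends on the grouping. Cd79b, a signalling chain of the B cell receptor, went from 2.12 ± 0.465 CPM to 171 ± 13.4 CPM. Fcrla rose by 7.04 ± 0.19 and Pou2af1, a transcriptional coactivator of B cells, by 5.04 ± 0.16 on the log2 scale. Rag1, which encodes a recombinase of antigen receptor genes, had no count in fl and was at least 191.1-fold higher in del. Cd38 was the member that did not rise (log2 fold change -0.79 ± 0.31, adjusted p = 0.052).

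Of the lists of cell type markers only the B cell list passed. The summed B cell markers were at 419 ± 29.8 CPM in fl and 4238 ± 65.1 CPM in del, and the summed myeloid markers at 695 ± 27.1 CPM and 2067 ± 36.9 CPM. Of 9 tested myeloid markers 6 rose and 3 fell, also adjusted over the list alone, and the list missed the threshold (median 2.06, adjusted p = 0.0511). It passed with upper-quartile factors (median 1.94, adjusted p = 0.0367), with no count filter (2.27, 0.00701), without fl replicate 2 (3.22, 0.0169), without fl replicate 3 (3.11, 0.017) and with the trend on transcript length and GC content removed (2.60, 0.0042). Among genes of at least 10 CPM in 3 libraries (4.21, 0.00542) and in thinned libraries (4.33, 0.00703) it passed with 7 members left to test. Itgam rose by 6.75 ± 0.28, Tyrobp by 4.32 ± 0.17 and Csf1r by 4.21 ± 0.19 on the log2 scale, while Cd14 was lower in del (log2 fold change -1.05 ± 0.40). Fibroblast markers, which the feeder cells would carry, summed to 59.9 ± 13.1 CPM in fl and 94.0 ± 35.1 CPM in del (highest in del replicate 2, at 134.5 CPM), with 5 of 8 tested members higher, 2 lower and no call for the list (adjusted p = 0.375). Adjusted over the list alone, 6 were higher and 2 lower. With no count filter, which left 33 members, the list passed (median 1.64, adjusted p = 0.0404). T and NK cell markers summed to 41.6 ± 2.34 CPM and 109 ± 11.1 CPM, with Cd2 at 13.1 ± 3.07 CPM in fl and 105 ± 10.1 CPM in del. Of 3 tested members Cd2 rose and Cd5 and Lck fell, also adjusted over the list alone, and the list was not called (adjusted p = 0.48). Erythroid markers summed to 0.497 ± 0.133 CPM and 0.602 ± 0.167 CPM, and that list was not tested.

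**Figure D1:**
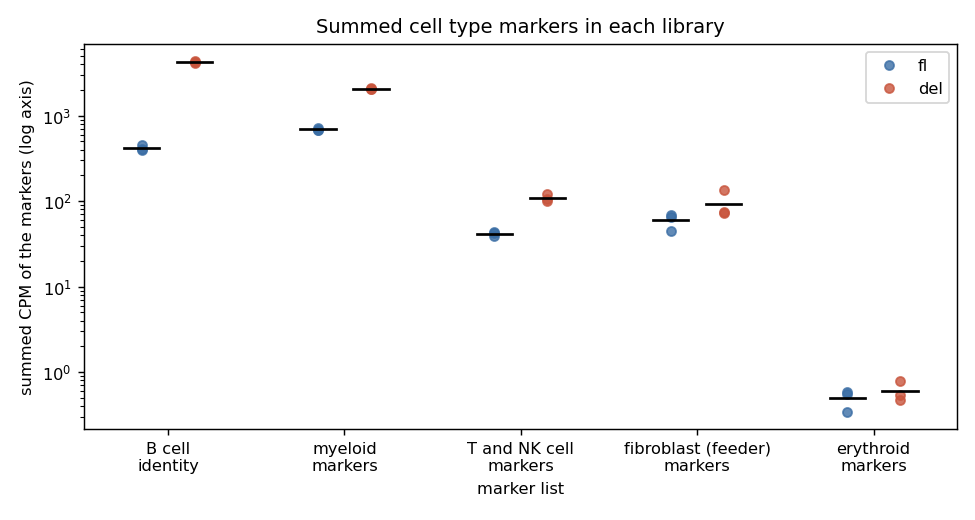
Summed CPM of the markers of 5 cell types on a log axis, 1 point per library and a black bar at the mean of the 3 libraries of each group. The B cell markers lie near 419 CPM in fl and 4238 CPM in del, and the erythroid markers lie below 1 CPM in both.

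Genes of glycolysis and of the response to low oxygen were lower in del. Of 19 tested glycolysis genes 15 fell and 1 rose, also adjusted over the list alone, with a median of -1.26 (camera, adjusted p = 4.36e-05), a call lost at adjusted p = 0.304 with an estimated correlation. Ldha, which encodes lactate dehydrogenase A, went from 2208 ± 204 CPM to 598 ± 21.8 CPM (log2 fold change -1.88 ± 0.13, adjusted p = 4.11e-06). Tpi1 went from 1110.4 ± 149.6 CPM to 248 ± 19.4 CPM, Gapdh from 1168 ± 154 CPM to 345 ± 7.84 CPM, and Aldoc fell by 4.38 ± 0.24 on the log2 scale. Pfkfb3, which encodes a regulator of phosphofructokinase, was the 1 gene that rose (log2 fold change 0.76 ± 0.22), and Hk2 was at 155 ± 17.1 CPM and 136 ± 17.3 CPM (adjusted p = 0.292). Of 17 genes of the HIF response 10 fell and none rose, also adjusted over the list alone (median -0.98, adjusted p = 0.00645, and adjusted p = 0.23 with an estimated correlation). They included Egln3, a prolyl hydroxylase gene (log2 fold change -4.49 ± 0.20), Bnip3 (-3.38 ± 0.17), Ndrg1 (-3.01 ± 0.18) and the glucose transporter gene Slc2a1 (-2.05 ± 0.18).

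**Figure D2:**
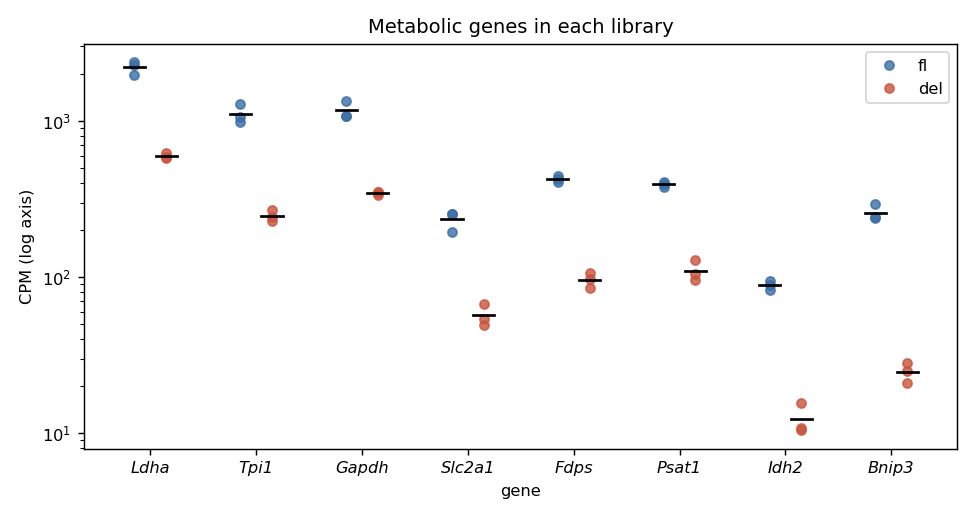
CPM of 8 metabolic genes on a log axis, 1 point per library and a black bar at the mean of the 3 libraries of each group. Every del library lies below every fl library for each gene shown, as for Ldha at means of 2208 and 598 CPM.

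Mitochondrial and biosynthetic genes were lower in del as well. Of 70 nuclear OXPHOS subunit genes 66 fell and none rose (median -0.83, adjusted p = 1.88e-11, and adjusted p = 0.23 with an estimated correlation). Of 25 genes of the TCA cycle and pyruvate entry 20 fell and 1 rose (median -0.60, adjusted p = 0.000519, and adjusted p = 0.24 with an estimated correlation), with Idh2, the mitochondrial NADP-dependent isocitrate dehydrogenase gene, at -2.83 ± 0.18. Of 21 sterol synthesis genes 17 fell and 1 rose (median -0.87, adjusted p = 0.00091, and adjusted p = 0.304 with an estimated correlation), and Fdps went from 427 ± 18.9 CPM to 96.4 ± 10.5 CPM. Of 16 genes of serine, glycine and one-carbon metabolism 13 fell and 1 rose (median -0.71, adjusted p = 0.00358, and adjusted p = 0.23 with an estimated correlation). Psph and Psat1, which encode enzymes of serine synthesis, stood at -2.37 ± 0.17 and -1.84 ± 0.15. Of 22 nucleotide synthesis genes 15 fell and 3 rose (median -0.70, adjusted p = 0.0157, and adjusted p = 0.304 with an estimated correlation), among them Dhodh and Umps of pyrimidine synthesis, which fell, and Dck of nucleoside salvage, which rose. Of 17 genes of glutamine, proline and polyamine metabolism 10 fell and 3 rose (median -0.75, adjusted p = 0.0428, and adjusted p = 0.392 with an estimated correlation). This last call was lost without del replicate 3 (adjusted p = 0.0704), with the replicate number as a block (0.0515) and among genes of at least 10 CPM in 3 libraries (0.0634). Counts adjusted over the list alone were the same for these 6 lists.

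Genes of the cytosolic ribosome fell by a similar amount. Of 81 ribosomal protein genes 73 fell and none rose, also adjusted over the list alone (median -0.91, adjusted p = 1.54e-12, and adjusted p = 0.286 with an estimated correlation). Rps20 went from 5515 ± 183 CPM to 2154 ± 63.6 CPM and Rpl22l1 fell by 3.56 ± 0.15 on the log2 scale. How reads shared with pseudogene copies were counted is not given in the sources used here, which leaves these levels uncertain. The longest annotated transcripts of these genes, which need not be those expressed, are short. Their median length was 1094 nucleotides for ribosomal proteins and 1025 for OXPHOS subunits. Across 10220 genes the fold change rose with this transcript length (Spearman's rho 0.407 across genes, which are not independent replicates). In the fifth of genes with the shortest transcripts the median log2 fold change was -0.67, and in that with the longest it was 0.81. With the trend on length and GC content removed, the ribosomal protein median was -0.38 (adjusted p = 0.000927) and the OXPHOS median -0.42 (adjusted p = 0.00144). Only 7 of the 67 histone genes in the list had enough counts in these oligo-dT primed libraries to be tested. They need not stand for histone transcripts as a whole. Of 7 tested histone genes 5 fell and 1 rose, also adjusted over the list alone (median -1.46, adjusted p = 0.0468, and adjusted p = 0.304 with an estimated correlation), and the call was lost without fl replicate 1 (adjusted p = 0.0662), del replicate 1 (0.0587), del replicate 2 (0.167) or del replicate 3 (0.102), with upper-quartile factors (0.0559), with no count filter (52 members, median -0.50, adjusted p = 0.124) and with the length and GC trend removed (median -0.96, adjusted p = 0.176).

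Interferon-response genes were higher in del as a list, and antigen presentation genes in part. Of 31 interferon-response genes 18 rose and 2 fell, also adjusted over the list alone (median 0.89, adjusted p = 0.00161, and adjusted p = 0.304 with an estimated correlation), with Parp14 at 4.70 ± 0.20 and Trim30a at 4.18 ± 0.22. Of 8 MHC class II genes 6 rose and 1 fell, also adjusted over the list alone (median 2.05, adjusted p = 0.0157, and adjusted p = 0.24 with an estimated correlation). Cd74, the invariant chain gene, rose by 1.78 ± 0.13 and H2-Aa by 3.26 ± 0.26 on the log2 scale, whereas H2-Ab1 fell by 1.41 (standard error 0.14). Among genes of at least 10 CPM in 3 libraries the class II list was not called (median 2.52, adjusted p = 0.171), nor in thinned libraries (median 2.38, adjusted p = 0.153), each time with 4 members left to test. The summed B cell and myeloid markers were at 4238 and 2067 CPM in del against 419 and 695 CPM in fl. The MHC class I list was not called (6 of 11 rose and 2 fell, also adjusted over the list alone, adjusted p = 0.0788), but was with no count filter (median 0.86, adjusted p = 0.0423) and with the length and GC trend removed (median 1.39, adjusted p = 0.00264).

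**Figure D3:**
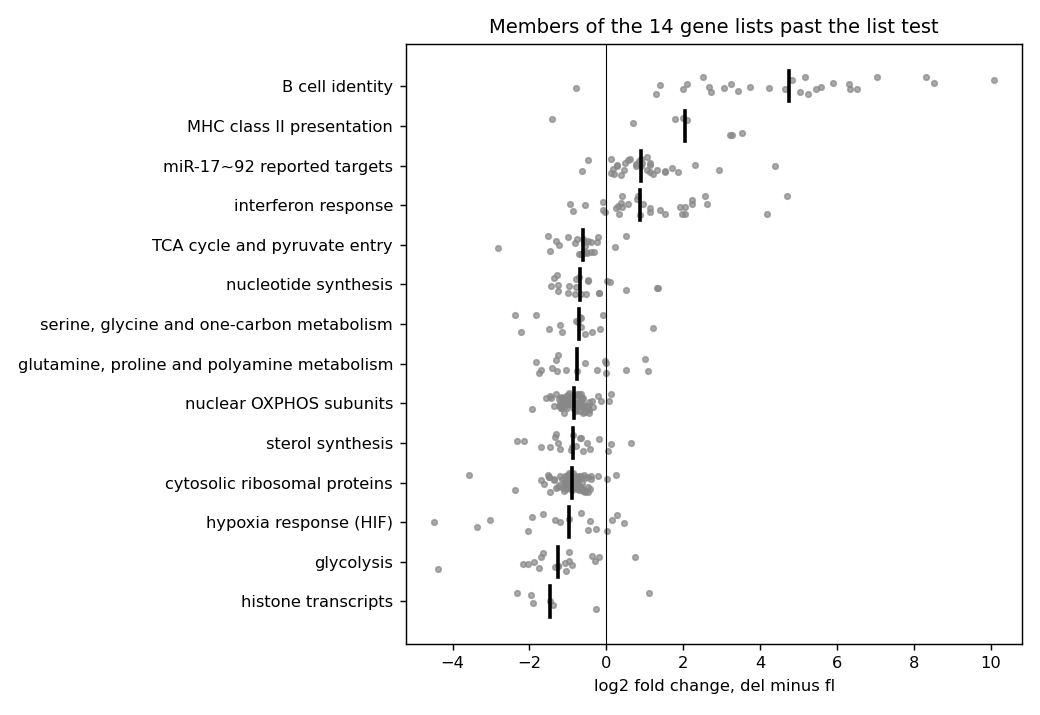
Log2 fold changes (del minus fl) of the tested members of the 14 gene lists past the list test, 1 point per gene and a black bar at the median of the list. B cell identity has the highest median (4.74) and histone transcripts, with 7 of 67 members tested, the lowest (-1.46).

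Transcripts reported as targets of the cluster were higher in del on balance. Of 33 tested members 23 rose and 1 fell, also adjusted over the list alone (median 0.90, adjusted p = 0.000401, and adjusted p = 0.169 with an estimated correlation). Tgfbr2, a TGF-beta receptor gene, went from 13.9 ± 1.57 CPM to 106 ± 15.3 CPM, and Ccnd1, the cyclin D1 gene, from 287 ± 42.9 CPM to 1420.5 ± 122 CPM. Trp53inp1 rose by 4.39 ± 0.42 and Ncoa3 by 1.71 ± 0.19 on the log2 scale. Among members named after their values were seen, Bcl2l11, a pro-apoptotic gene, rose by 1.13 ± 0.16 on the log2 scale, while Ccnd2 was the 1 that fell (log2 fold change -0.63 ± 0.17). Members of this list are long, with a median of 4924 nucleotides for the longest annotated transcript. The central 95% of lists matched to this list on length and expression had medians of 0.08 to 0.92. With the length and GC trend removed its median was 0.45 (adjusted p = 0.0409).

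Seed sites of the 4 families of the cluster were tested in the 3' UTRs, each family against control heptamers and not against the others. Genes with a 7-base site of miR-92a (GTGCAAT, 789 of 9860 genes) had a fold change 0.29 higher on the log2 scale than other genes of like UTR length, GC content and expression. None of 449 control heptamers gave as large a t statistic, the coefficient over its standard error (adjusted p = 0.00889, the smallest these controls can give). Each of the 9 other splits of the libraries into 3 and 3 also called 1 to 3 families. Passing this threshold is thus not particular to the grouping into fl and del. Those splits keep part of the difference between fl and del, so they do not show whether the call depends on it. The coefficient was 0.10 for miR-17/20a (GCACTTT, 1508 genes, adjusted p = 0.0936), 0.04 for miR-19a/b (TTTGCAC, 1392 genes, adjusted p = 0.499) and -0.04 for miR-18a (GCACCTT, 1014 genes, adjusted p = 0.517). Without del replicate 3, miR-17/20a also passed, with a coefficient of 0.11 (adjusted p = 0.0468).

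**Figure D4:**
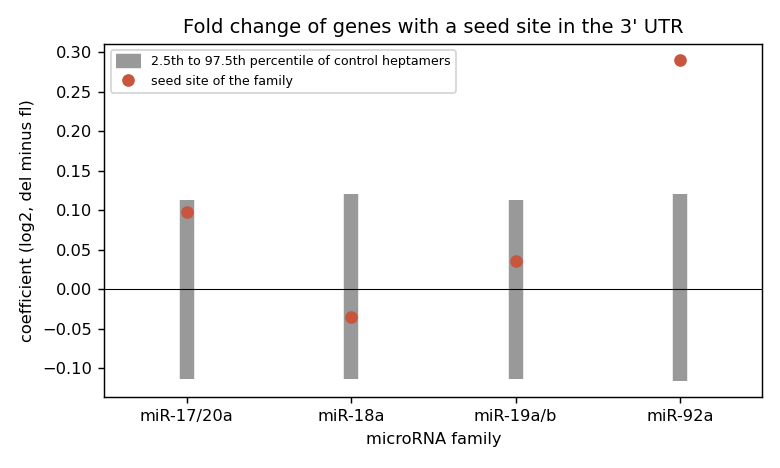
Coefficient of the log2 fold change (del minus fl) on the presence of a seed site in the 3' UTR for the 4 families (points), with the central 95% of control heptamers (grey bars). The miR-92a point, at 0.29, lies above its bar, and the others lie within theirs.

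The remaining lists did not pass. Signalling genes moved both ways: of 27 mTOR, PI3K and AMPK genes 12 rose, with Pik3r1 at 2.72 ± 0.25, and 6 fell, with the translation repressor gene Eif4ebp1 at -1.78 ± 0.14 (adjusted p = 0.247). Adjusted over the list alone, 12 rose and 7 fell. Of 18 p53 targets 10 rose, among them the antiproliferative gene Btg2 at 62.9 ± 11.2 CPM in fl and 357 ± 41.6 CPM in del, and 2 fell (10 and 3 adjusted over the list alone, adjusted p = 0.0519, but 0.0417 without fl replicate 2, 0.0373 among genes of at least 10 CPM in 3 libraries and 0.0324 in thinned libraries). Of 20 BCL2 family and caspase genes 5 rose, with Bcl2 at 2.53 ± 0.18, and 8 fell, with the pro-apoptotic gene Pmaip1 at -1.88 ± 0.25 (adjusted p = 0.451). Of 25 mitotic genes 8 rose and 9 fell (adjusted p = 0.801), and of 28 replication genes 7 rose and 11 fell (adjusted p = 0.668). Of 38 ribosome biogenesis and MYC target genes 9 rose and 12 fell (adjusted p = 0.461). Of 22 lysosome and autophagy genes 10 rose and 6 fell (adjusted p = 0.158), with the lysosomal protease genes Ctsd at 2.74 ± 0.14 and Ctsl at -1.92 ± 0.13. For these lists from BCL2 to lysosome the counts adjusted over the list alone were the same.

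Of 16 genes of the integrated stress response 4 rose, among them Ddit3 at 3.04 ± 0.25, and 9 fell, among them Trib3 at -2.28 ± 0.22 (4 and 10 adjusted over the list alone, adjusted p = 0.119). Of 14 genes of the unfolded protein response 8 rose, with the chaperone gene Calr at 2.07 ± 0.22, and 5 fell, with the transcription factor gene Xbp1 at -1.09 ± 0.15 (9 and 5 adjusted over the list alone, adjusted p = 0.375). Of 18 NF-kB targets 6 rose, with the chemokine genes Ccl3 and Ccl4 among them, and 7 fell, with Traf1 at -3.34 ± 0.20 (6 and 8 adjusted over the list alone, adjusted p = 0.708). Counts adjusted over the list alone were the same for the lists that follow. Of 7 pentose phosphate genes 5 fell and none rose (adjusted p = 0.147), but with the length and GC trend removed Taldo1 turned to 0.05 (adjusted p = 0.775) and Pgls lost its call (adjusted p = 0.0919). Of 17 fatty acid oxidation genes 8 fell and 1 rose (adjusted p = 0.172), and of 15 fatty acid synthesis genes 7 fell, the desaturase gene Fads1 among them, and 3 rose (adjusted p = 0.375). The nuclear-retained RNAs Malat1, Neat1 and Kcnq1ot1 all rose (adjusted p = 0.112), but with the length and GC trend removed Neat1 was at -0.09 and Malat1 missed the threshold (adjusted p = 0.0971), as Malat1 did with no count filter (adjusted p = 0.071). Of 10 immediate early genes 3 rose and 5 fell (adjusted p = 0.425), and of 6 heat shock genes 1 rose and 2 fell (adjusted p = 0.972). The median, mean and test differed in sign for the replication, mitosis, NF-kB and heat shock lists.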

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

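The thinned libraries and the removal of the length and GC trend were chosen after the data were seen, and the other alternatives before. Called genes numbered 5488 to 7286 under the other filters and scalings, 6839 with DESeq2 (which left 2206 genes without an adjusted p), 6673 with limma-voom, 5649 with thinned libraries and 6049 to 6479 with each library left out. The median of all genes was -0.131 with upper-quartile factors, against -0.00346 with TMM, and the higher share of the calls 44.0%. With glmTreat against a log2 fold change of 0.5, 2219 genes were lower in del, since that test asks for a larger change. With an estimated correlation 0 of the 34 lists passed, and with fry, which does not compare a list with other genes, 28 did. Calls were lost also where the estimate lay below the preset 0.01. These were the reported targets (-0.0148), serine and one-carbon (-0.0146), class II (-0.0821) and HIF (0.00702) lists. For them a higher correlation cannot be the reason for the loss. The other called lists had estimates above 0.01. Since this setting also lost calls without a higher correlation, their loss cannot be put down to correlation alone. Leaving out each library gave 12 to 16 lists. Seed-site families past the threshold numbered 1 to 2 with each library left out, and the miR-17/20a coefficient was 0.0851 to 0.113, past the threshold without del replicate 3. The cause was not tested. With the length and GC trend removed, 6047 genes were called and Taldo1 (0.04763) and Neat1 (-0.09241) changed sign and missed the threshold. Their direction thus depended on the trend. Of the values of named genes under the alternatives, 2434 kept their direction and side of the threshold, 9 lost and 3 gained the call; of those of single lists, 486 kept it, 26 lost it (14 with an estimated correlation) and 27 gained it. The numbers do not pair the samples (deviation correlations 0.103, -0.0515 and -0.0185), and a fit with the replicate number as a block called 6510 genes and 13 lists. The del libraries, at 2121796 to 3738720 counts, set the depth at which low genes can be seen.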

Other observations

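The 3 cell mixture tests, the seed coefficients across splits, the thinned libraries and the gene families were chosen after the result was seen, and the transcript length and chromosome tests were thought of once the fold changes were known but fixed before they were run.

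The gene families given here were chosen because their members had been seen to move, so no test bears on them and the counts only describe them. Of 78 mitochondrial ribosomal protein genes 68 fell in del and none rose (median -0.92). Fold changes rose with transcript length across genes, and the families given here were not matched on length. Of 37 proteasome subunit genes 26 fell and 1 rose, Psmb9. Of 9 p200 family genes, which encode interferon-inducible DNA sensors and regulators, 8 rose and none fell, with Ifi207 at 80.7 ± 7.47 CPM in del and 1.01 ± 0.292 CPM in fl.

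Genes that mark cell types differed between the groups in both directions. If the fl libraries were del-type cells mixed with others, genes abundant in del would keep part of their level in fl, but 72 of 3437 genes with at least 50 CPM in del lay under 5% of it in fl, which argues against such cells as 5% or more of the fl RNA. For the mirror case, 15 of 3212 genes lay under 5%, between the bounds of 5 and 20 that had been set, and 11 of them did so by more than the spread between libraries and the counting error, among them Epcam (0.103% of its fl level), Krt18 (0.283%) and Afp (0.245%). This argues against fl-type cells as 5% or more of the del RNA, while a trace of them may be present and cannot be told apart here. Direct loss of repression may add to the genes at least 4-fold higher in del, of which 41.5% carry a seed site against 39.2% of matched genes (percentile 96.6), a difference inside the matched range, and selection of a subclone or an exchange of cell lines stays open and untested.

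Ribosomal protein, OXPHOS and metabolic lists were lower in del, and short transcripts were lower as a whole. For the ribosomal protein and OXPHOS lists, 2 of 2 medians lay below lists matched on transcript length and expression, but OXPHOS by less than its own spread (-0.8329 against -0.8314, bootstrap SE 0.0582), and a simulated length trend alone also put the ribosomal proteins below their range. With the trend on length and GC content removed, both lists kept their calls at smaller medians (-0.38, adjusted p = 0.000927, and -0.42, adjusted p = 0.00144). Length may thus account for part or all of these falls and cannot be told apart from a shift of their own. Of the other 8 lists called lower, 6 lay below their matched range. Serine and one-carbon (-0.7119 against -0.5383, bootstrap SE 0.1921) and glutamine and proline genes (-0.7535 against -0.5527, SE 0.4141) did so by less than their own spread. For glycolysis, sterol synthesis, HIF and nucleotide synthesis the gap was larger than the spread, which argues against length as the whole cause there. TCA and histone genes lay inside their range. With the trend on length and GC content removed, the TCA list kept its call (median -0.45, adjusted p = 0.00349) and the histone list did not. No single library made the length trend, whose slope kept at least 96.5% of its value with any library left out. Whether the trend came from the RNA, the library preparation or the cells was not tested, since every library of a group shares it.

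Median fold changes also differed by chromosome. Among 6044 genes with a mean of at least 20 CPM, 6 of 20 chromosomes lay outside expression-matched random sets (adjusted p under the threshold of 0.05), with chromosome 9 at 0.56 and chromosome 19 at -0.55. All 6 segments, 3 of like gene number on each, lay outside the random range in the same direction as the whole, as a change in copy number of the whole chromosome could give, and this is offered as a hypothesis. After regression on transcript GC content and length, chromosome 9 kept 56.8% and chromosome 19 103% of its median. Among the other 4, chromosome 3 kept 152%, chromosome 8 124% and chromosome 17 98.2%, while chromosome 1 turned from 0.17 to -0.10. These shares are distances from 0, but the adjusted medians of most chromosomes lay lower. Examples are chromosomes 2 (0.04 to -0.06) and 14 (-0.09 to -0.39), while chromosomes 7 and 17 lay slightly higher. A downward move common to the adjusted medians lowers the share kept above 0 and raises that kept below 0. How much of each shift composition gives cannot be told from these shares. Of chromosomes 9 and 19, only chromosome 9 lay outside its range among genes changed less than 2-fold. Leaving out the larger changes takes away part of the shift itself. Whether clustered identity genes gave the shift thus cannot be told apart from dosage on either of these chromosomes.

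With all libraries thinned to the shallowest total, 5649 genes were called, 5523 of them among the original 6676, which argues against depth as the main cause of the number of calls. The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. For genes, 1 of the 10 splits (the real one) gave as many as 6676, and the highest other gave 0 with edgeR (15 to 112 genes at an unadjusted p under 0.05, and 0 with limma-voom). Each of those splits mixes fl and del libraries within both groups, which widens the spread within groups. The 0 genes called there can follow from this mixing alone and give no measure of chance. For lists, 2 of the 10 splits gave as many as 14, the highest other being 14. Every other split called 6 to 14 lists, so passing the list threshold is not particular to the grouping into fl and del. Since the other splits keep part of the difference between fl and del, they do not show whether a given call depends on it. For seed sites, 1 of the 10 gave a coefficient as large as 0.29, the highest other being 0.089, although each of the other splits called 1 to 3 families.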
